A study of Mus musculus with 16 samples.

How the data were processed

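Total RNA from mouse hippocampus was sequenced in 16 libraries, 4 in each combination of genotype (wild type or Tspo knockout) and injection (PBS or LPS). Groups and replicate numbers were taken from the deposited labels. The deposited table holds, per the submitters' processing notes, an estimated count for each gene and library, rounded to whole numbers; those notes name MultiQC 1.13, Salmon 1.9.0, DESeq2 and DESeq without giving each tool's part. The table listed 19449 genes, each with a sum of at least 10 over the libraries, and every value was whole. Gene symbols and positions came from GENCODE M21 on GRCm38; 105 identifiers, holding 0.054% of the counts, were absent from it.

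Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 16269 genes and 99.97% of the counts and removed 3180. Libraries were scaled by TMM, and a quasi-likelihood negative binomial model with a mean for each group was fitted over all 16 libraries; the biological coefficient of variation was 0.177. The 4 pairwise comparisons and the genotype by treatment interaction were tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The SE of a log2 fold change is its size divided by the root of its F statistic. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Differences in Tspo log2 CPM and in the leukocyte list score were also tested by exact two-sided permutation tests. Library totals ran from 30198619 to 50009041 counts. The reads carry no molecular identifiers, and the spread between libraries, not the depth, sets the errors given.

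Before the data were examined, 44 gene lists, the comparisons, the rule for naming genes and most of the other settings were fixed. The rule named Tspo and, for each comparison, up to 10 genes per direction with the largest change. These had to pass, to have a mean log2 CPM of at least 1 and groups that did not overlap, and not to be predicted or sex-linked genes. It also named the 10 interaction genes with the smallest p, and of each list described up to 4 members that passed with the smallest p. Of the lists, 43 were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry; the sex-linked genes served only to read the sex of each library. A list score is the mean log2 CPM of its genes relative to the wild-type PBS mean. The SE of a correlation between effects across genes is a jackknife over libraries within groups, and its p comes from 100 permutations of the labels.

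The results were recomputed with RLE scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no filter and a filter of CPM of at least 1 in 4 libraries. They were also recomputed with the replicate number as a block, sex or 1 surrogate variable (sva 3.50.0) as a covariate, a fit of only the 8 libraries compared, and leaving out each library. Summing wild-type PBS replicates 2 and 3, and setting aside 3 libraries that differed in choroid plexus or cerebellar transcripts, were chosen after seeing the data. The pipeline was tested on simulated data of the same size. Shared 31-base words between transcripts were counted in the GENCODE M21 sequences.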

Results

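The series measured RNA from the hippocampus of 3-month-old mice that were either wild type or carried a deletion of Tspo, the gene of the translocator protein in the outer mitochondrial membrane, whose level is widely read as a marker of activated glia. Mice of each genotype had been injected with PBS, the vehicle, or with lipopolysaccharide (LPS), a bacterial cell wall component that sets off inflammation through the receptor TLR4. The labels give neither the dose of LPS nor the time between injection and tissue collection. Each of the 4 groups held 4 libraries. Their total counts ran from 30198619 to 50009041. Between 18195 and 18657 genes had at least 1 count in a library. No source says whether the replicates of a group are separate animals, so every p-value below measures the spread between these libraries, and n counts libraries. The titles carry codes of unstated meaning. Wild-type PBS replicates 1, 2 and 3 share a code, wild-type LPS replicates 2, 3 and 4 share another with the library labelled knockout PBS replicate 4, wild-type PBS replicate 4 shares its code with wild-type LPS replicate 1, and knockout LPS replicate 1 with replicate 2. Most of the comparison within wild type is therefore also a comparison of codes. The other comparisons are so entirely: no code is shared between the genotypes within a treatment, or between PBS and LPS in the knockout.

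Tspo itself (ENSMUSG00000041736; chromosome 15, 83563592 to 83574203 on the plus strand of GRCm38 in the GENCODE M21 annotation) stood at 3.09 ± 1.41 CPM (counts scaled to library size) in wild-type PBS and 8.51 ± 4.06 CPM in wild-type LPS (mean ± SD, n = 4 each). The authors' genome build is not given in the sources used here. It stood at 0.334 ± 0.12 CPM in knockout LPS (n = 4), with 7 to 20 counts per library. Of the 4 libraries labelled knockout PBS, 3 held 5, 10 and 14 counts (0.152, 0.28 and 0.47 CPM), but the library labelled knockout PBS replicate 1 held 98 counts, or 2.33 CPM, inside the wild-type PBS range of 2.06 to 5.17 CPM. Its Tspo level goes against its label, and every direction drawn below from the knockout PBS group includes it. Under LPS, Tspo was lower in the knockout by 4.64 on the log2 scale (log2 fold change -4.64 ± 0.73, SE; adjusted p = 0.00308, edgeR; exact two-sided permutation p on log2 CPM = 0.0286, the smallest that 4 against 4 libraries can give). Under PBS the difference of -1.89 ± 0.65 did not pass (adjusted p = 0.918, exact permutation p = 0.0571). Without the library labelled knockout PBS replicate 1 it was -3.37 and did not pass (adjusted p = 0.0881). In wild type the LPS libraries were higher by a log2 fold change of 1.46 ± 0.6, which did not pass either (adjusted p = 0.147; exact permutation p = 0.0571). It passed without wild-type LPS replicate 1 (1.76, adjusted p = 0.0389) and without the library labelled knockout PBS replicate 1 (1.46, adjusted p = 0.0456). The 4 wild-type LPS libraries held 2.63, 11.9, 9.4 and 10.1 CPM, so replicate 1 of that group lay at the PBS level. In the knockout the change of Tspo from PBS to LPS did not pass (-1.29 ± 0.73, adjusted p = 0.706) and was 0.18 without the library labelled knockout PBS replicate 1.

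**Figure D1:**
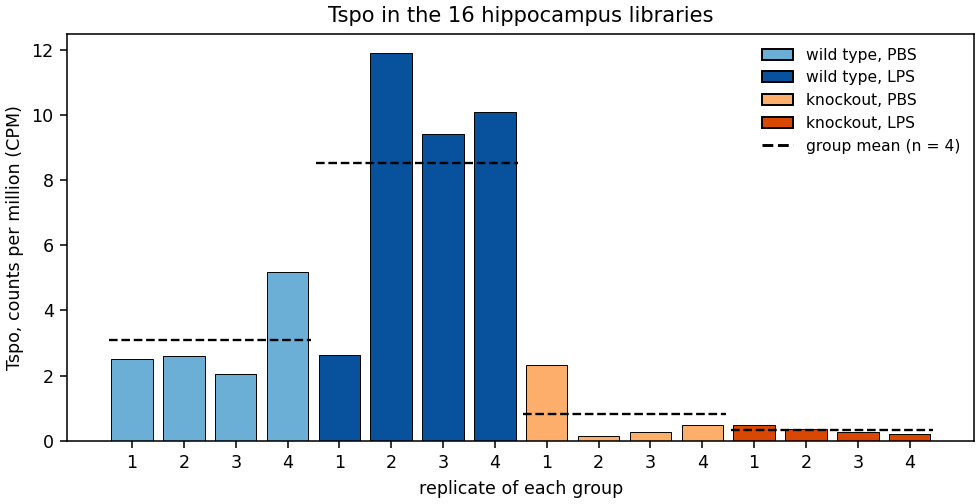
Tspo in CPM for each of the 16 libraries, with the group means as dashed lines (n = 4). The library labelled knockout PBS replicate 1 lies at 2.33 CPM while the other knockout libraries lie at or below 0.486 CPM, and wild-type LPS replicate 1 lies at 2.63 CPM beside 9.4 to 11.9 CPM in the rest of its group.

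In the wild-type hippocampus, the comparison of LPS with PBS asks which genes respond to the challenge. Lcn2, which encodes the iron-binding acute-phase protein lipocalin-2, rose from 0.127 ± 0.0964 to 171 ± 115 CPM (mean ± SD, n = 4; log2 fold change 10.37 ± 1.38, SE; adjusted p = 0.00251). Cfb, complement factor B, rose by 5.24 ± 0.87 from 0.216 ± 0.0613 CPM, and Icam1, the endothelial adhesion molecule that leukocytes bind, by 3.2 ± 0.51 (adjusted p = 0.00377 and 0.00343). The interferon-induced genes Ifitm1 (a membrane protein that blocks virus entry), Gbp6 and Iigp1 (GTPases that attack microbe-bearing vacuoles) rose by 2.9 ± 0.44, 2.69 ± 0.44 and 2.6 ± 0.43. H2-Q6, a non-classical MHC class I gene, rose by 2.88 ± 0.42, the gut hormone receptor gene Glp2r by 2.71 ± 0.38, the secreted phospholipase gene Pla2g3 by 2.43 ± 0.42 and the stress kinase gene Map3k6 by 2.35 ± 0.37. Gbp6, Iigp1, Ifitm1 and H2-Q6 belong to families of similar sequence, so reads can be divided among copies and their separate levels are uncertain. Among the largest falls were those of Wnt9b (a secreted signalling protein, -2.76 ± 0.68) and Nexn (an actin-binding protein, -2.24 ± 0.54). Mrvi1, a regulator of calcium release, fell too (-1.81 ± 0.44), and so did Plekhg1, a guanine nucleotide exchange factor gene (-1.77 ± 0.41). They were followed by the transcription factor gene Lef1 (-1.76 ± 0.36), Ugt8a, the enzyme that makes the myelin lipid galactocerebroside (-1.75 ± 0.23), and the methyltransferase gene Smyd1 (-1.71 ± 0.27). The last were the actin regulator gene Eps8l2 (-1.68 ± 0.32) and the matrix gene Hmcn1 (-1.59 ± 0.38).

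Across the 16269 genes tested, 768 rose and 626 fell in wild type after LPS. In 1403 genes (8.62%) the 4 LPS libraries lay apart from the 4 PBS libraries, where chance gives 2.86%. Of 43 lists tested in this comparison, the preset correlation called 23, fry 16 and an estimated correlation 1. Of 37 measured interferon-stimulated genes, 31 rose, 0 fell and 6 did not pass, and 35 rose when adjusted over the list alone (adjusted p = 0.317 with an estimated correlation). Ifi204, a DNA sensor, rose by 4.69 ± 0.68, and Ifit1, which binds foreign RNA, by 2.26 ± 0.36. Of 20 complement genes, 15 rose and 0 fell (17 adjusted over the list alone; adjusted p = 0.317 with an estimated correlation), among them C1ra (2.59 ± 0.45), C1qb (1.26 ± 0.23) and the C5a receptor gene C5ar1 (2.69 ± 0.5). Of 30 genes of reactive astrocytes, 19 rose (21 adjusted over the list alone; adjusted p = 0.317 with an estimated correlation), with the protease inhibitor gene Timp1 at 5.15 ± 0.79 and the GTPase gene Gbp2 at 3.24 ± 0.5. The 28 genes of TLR4 signalling and its NF-kappaB targets held 13 that rose (18 adjusted over the list alone; adjusted p = 0.317 with an estimated correlation), such as the cytokine brake Socs3 (1.69 ± 0.29) and the NF-kappaB cofactor Bcl3 (3.25 ± 0.61). In antigen presentation 13 of 22 rose (14 adjusted over the list alone; adjusted p = 0.317 with an estimated correlation), including the MHC class I regulator Nlrc5 (3.01 ± 0.49) and the transporter-loading gene Tapbp (1.14 ± 0.2). Of 10 measured cytokines and chemokines, 7 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.361 with an estimated correlation). The monocyte attractant Ccl12 rose by 3.9 ± 0.68 and the neutrophil attractant Cxcl1 by 5.58 ± 1.15, while Cxcl12 fell (-0.77 ± 0.14).

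Activated microglia genes rose in 14 of 27 cases (17 rose and 1 fell adjusted over the list alone; adjusted p = 0.443 with an estimated correlation). The scavenger receptor gene Msr1 rose by 5.65 ± 0.86 and the Fc receptor gene Fcgr3 by 1.51 ± 0.25. Of 16 genes of resting microglia, 4 fell and 1 rose (8 and 4 adjusted over the list alone; adjusted p = 0.443 with an estimated correlation). The purinergic receptor gene P2ry12 fell by 1.35 on the log2 scale (-1.35 ± 0.33) and the integrin gene Itgam rose by 1.29 ± 0.27. Activated endothelium genes rose in 12 of 18 cases, the count also being 12 adjusted over the list alone (adjusted p = 0.317 with an estimated correlation), as in Ch25h (4.04 ± 0.64), which oxidises cholesterol, and Lrg1 (3.58 ± 0.57), a secreted glycoprotein. Glucocorticoid-responsive genes rose in 16 of 24 cases (19 adjusted over the list alone; adjusted p = 0.317 with an estimated correlation), as in the cell cycle inhibitor Cdkn1a (2.2 ± 0.38) and the metallothionein gene Mt1 (1.56 ± 0.29). Of 14 neutrophil, monocyte and lymphocyte genes, 7 rose (8 adjusted over the list alone), and this list alone kept its call with an estimated correlation (adjusted p = 0.0489). Its members S100a8 (5.3 ± 1.07), S100a9 (4.37 ± 0.91) and the neutrophil granule gene Ngp (3.62 ± 0.85) stayed below 7 CPM in every library. Of 8 red blood cell genes 1 fell in the same comparison (7 adjusted over the list alone; median log2 fold change -2.56; adjusted p = 0.317 with an estimated correlation). Oligodendrocyte and myelin genes fell in 13 of 20 cases (17 adjusted over the list alone; adjusted p = 0.317 with an estimated correlation), with the myelin surface protein gene Mog at -1.28 ± 0.18. Marker genes of neighbouring brain regions fell in 6 of 26 cases in the same comparison (6 adjusted over the list alone; adjusted p = 0.525 with an estimated correlation). Their list scores were -0.88 to -0.65 in the wild-type LPS libraries and -0.51, 0.51, 0.53 and -0.54 in wild-type PBS replicates 1 to 4. Cholesterol synthesis genes fell in 11 of 25 cases (18 adjusted over the list alone; adjusted p = 0.317 with an estimated correlation), with Nsdhl and Dhcr7 both at -0.58. Of the 20 genes that bind TSPO or make neurosteroids, 2 fell and 0 rose (4 fell adjusted over the list alone; list test adjusted p = 0.19). These were the steroid reductase gene Srd5a1 (-0.46 ± 0.11) and the TSPO-associated Golgi protein gene Acbd3 (-0.24 ± 0.06).

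The inflammatory rise came from wild-type LPS replicates 2, 3 and 4. Lcn2 stood at 238, 209 and 237 CPM in them and at 0.641 CPM in replicate 1, and their interferon list scores were 2.2, 2.15 and 2.03 against -0.04 (log2, relative to wild-type PBS). Replicate 1 nevertheless shared part of the falls, with Ugt8a at 39 CPM and Mog at 36.8 CPM, below the wild-type PBS ranges of 62.6 to 88.2 and 62.3 to 80 CPM. Its Glp2r level of 8.06 CPM lay between the PBS range of 1.07 to 4.29 and the 13.2 to 20.3 CPM of the other 3. Wild-type LPS replicate 1 also had low choroid plexus and ependymal scores (-3.05 and -2.24), as had wild-type PBS replicate 1 (-2.94 and -2.11). The oligodendrocyte score of that PBS library was the lowest of its group (-0.36). The low myelin genes of wild-type LPS replicate 1 thus cannot be told apart from a difference in tissue composition. In wild-type LPS replicates 2, 3 and 4 the oligodendrocyte scores were -0.38, -1.05 and -1.4, so that replicate 2 lay near that PBS library. Tissue composition was not tested as a source of their fall. Leaving out wild-type LPS replicate 1 raised the count of called genes from 1394 to 3380, while leaving out wild-type PBS replicate 2 or 3 gave 625 or 621 and wild-type LPS replicate 2, 3 or 4 gave 758, 538 or 694. A fit of these 8 libraries alone called 0 genes with edgeR, with 3012 at an unadjusted p below 0.05, against 2150 called by DESeq2 and 4684 by limma-voom with sample weights over all 16 libraries.

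**Figure D2:**
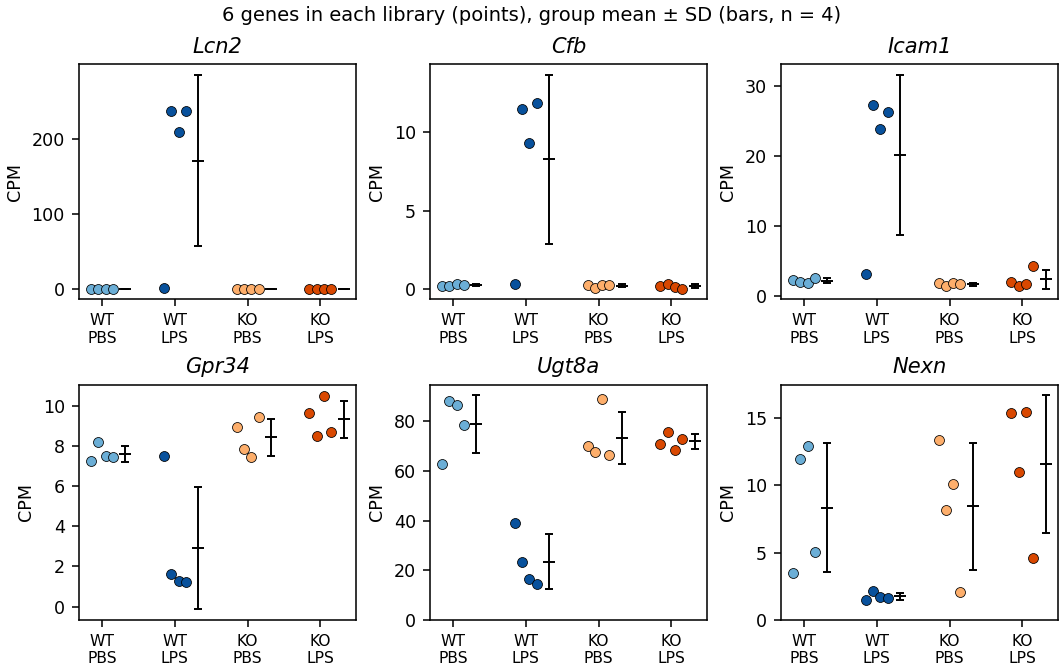
CPM of 6 genes in each library (points) with the group mean ± SD (n = 4) for wild type (WT) and knockout (KO) after PBS or LPS. Lcn2, Cfb and Icam1 were high only in wild-type LPS replicates 2, 3 and 4, whereas Ugt8a and Nexn were low in all 4 wild-type LPS libraries.

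In the knockout, the same comparison asks whether the response to LPS persists without TSPO. Lcn2 stood at 0.0572 ± 0.0662 CPM after LPS and 0.111 ± 0.129 CPM after PBS (mean ± SD, n = 4), Cfb at 0.155 ± 0.134 and 0.203 ± 0.115 CPM, and Icam1 at 2.34 ± 1.34 and 1.66 ± 0.236 CPM. None of the 16269 genes passed with edgeR (0 called, 1120 at an unadjusted p below 0.05, smallest adjusted p = 0.703), DESeq2 called 3 and limma-voom with sample weights 0. The LPS and PBS libraries lay apart in 1065 genes (6.55%; chance gives 2.86%). In simulated data, 55 of 67 changes of 2-fold (82.1%) and 62 of 66 changes of 4-fold (93.9%) were recovered in this comparison. The simulation drew genes independently, without tissue differences between libraries, so these rates do not measure what share of real changes would be found. The 768 genes that rose in wild type had a median log2 fold change of 0.81 there and of -0.05 in the knockout, where 282 of them (36.7%) were higher after LPS; the 626 that fell had medians of -0.49 and 0.01. Of the 37 interferon-stimulated genes 0 rose and 0 fell, also adjusted over the list alone (list test adjusted p = 0.736). The leukocyte list score was 0.43 ± 0.25 after LPS and 0.08 ± 0.2 after PBS (mean ± SD, n = 4; exact two-sided permutation p = 0.0571). S100a8 held 0, 0.146, 0.356 and 0.715 CPM in the 4 knockout LPS libraries and at most 0.134 CPM in those labelled knockout PBS.

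List tests with the preset correlation called 7 of 43 lists in the knockout, and 0 with an estimated correlation. Genes of neighbouring brain regions were higher after LPS (median log2 fold change 0.66; adjusted p = 1.28e-05, and 0.402 with an estimated correlation). Circadian clock genes were higher as well (0.13; adjusted p = 0.000191, and 0.402 with an estimated correlation). So were immediate early genes (0.27; adjusted p = 0.00187, and 0.997 with an estimated correlation) and genes of the mitochondrial genome (0.14; adjusted p = 0.000879, and 0.997 with an estimated correlation). Knockout LPS replicate 4 stood apart in both: its immediate early score was 0.54 against -0.36, -0.15 and -0.15 in replicates 1 to 3 and -0.5 to -0.01 in the libraries labelled knockout PBS. Its mitochondrial score was -0.24 against 0.3, 0.19 and 0.4, and -0.06 to 0.06. Nuclear genes of oxidative phosphorylation (-0.04), ribosomal proteins (-0.06) and fatty acid oxidation (-0.1) were lower, each with an adjusted p of 0.997 with an estimated correlation. In these 7 lists 0 members passed over all genes, and adjusted over the list alone 1 immediate early gene rose. Without the library labelled knockout PBS replicate 4, 1 gene was called, and without the library labelled knockout PBS replicate 2 the list count was 11.

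Under LPS, the comparison of knockout with wild type asks what TSPO loss changes in the challenged hippocampus, using the same wild-type LPS libraries as the comparison within wild type. Lcn2 was lower in the knockout (-11.58 ± 1.5, adjusted p = 0.00308), as were Cfb (-5.65 ± 0.88), and Tspo itself. Lower interferon-induced genes were Gbp4 (-3.87 ± 0.56), Gbp2 (-3.35 ± 0.51), Ifitm3 (-3.16 ± 0.47), Ifitm1 (-3.02 ± 0.44). Further ones were Oasl2 (an antiviral sensor of RNA, -2.91 ± 0.43) and Gbp5 (an activator of the inflammasome, -2.87 ± 0.47). H2-Q6 was lower by 3.62 on the log2 scale (-3.62 ± 0.44). Higher in the knockout were Tnnt1 (slow troponin T, 3.23 ± 0.78), Nexn (2.72 ± 0.54), Wnt9b (2.21 ± 0.67), Synpo2 (an actin-bundling protein, 1.93 ± 0.6) and Gpr34, a lysophosphatidylserine receptor of microglia (1.7 ± 0.43). The histone gene Hist1h4i (1.65 ± 0.35), the protease inhibitor gene Serpinb1a (1.64 ± 0.24), Ugt8a (1.62 ± 0.23) and the peptide hormone gene Apln (1.56 ± 0.34) were higher too. Hist1h4i has copies of nearly equal sequence and is uncertain for the same reason as the Gbp and Ifitm genes.

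Over all genes, 750 were higher and 1185 lower in the knockout under LPS, and in 2331 genes (14.3%) the groups lay apart, where chance gives 2.86%. Lower were 34 of 37 interferon-stimulated genes (36 adjusted over the list alone), 15 of 20 complement genes (17) and 21 of 30 reactive astrocyte genes (23). The same held for 13 of 28 TLR4 and NF-kappaB genes (21), 15 of 22 antigen presentation genes (17) and 7 of 10 cytokine and chemokine genes (7). It also held for 13 of 18 activated endothelium genes (14) and 15 of 24 glucocorticoid-responsive genes (18). Each of these lists had 0 members higher and was called with the preset correlation and with fry. With an estimated correlation each had an adjusted p of 0.334. Of 43 lists tested in this comparison, the preset correlation called 23, fry 21 and an estimated correlation 0. Higher were 13 of 20 oligodendrocyte genes (13 adjusted over the list alone) and 11 of 25 cholesterol synthesis genes (17), both with an adjusted p of 0.334 with an estimated correlation. Of 26 marker genes of neighbouring brain regions 4 were higher and 0 lower (5 adjusted over the list alone, adjusted p = 0.334 with an estimated correlation), with a larger median log2 fold change than the 0.66 of oligodendrocyte genes. Choroid plexus and ependymal genes had medians of 0.97 and 0.59 (adjusted p = 0.563 and 0.56 with an estimated correlation). Their scores in wild-type LPS replicate 1 were -3.05 and -2.24. Of 16 genes of resting microglia 7 were higher and 2 lower (8 and 2 adjusted over the list alone, adjusted p = 0.334 with an estimated correlation). Of 27 activated microglia genes 1 was higher and 15 lower (2 and 16, adjusted p = 0.473 with an estimated correlation). The interleukin gene Il1b (-2.45 ± 0.44), Socs3 (-1.88 ± 0.3) and the complement protease gene C1s1 (-2.05 ± 0.34) were lower, and P2ry12 (1.47 ± 0.33), Mog (1.06 ± 0.18) and Nsdhl (0.42 ± 0.08) higher. Among the genes that bind TSPO or make neurosteroids, Acbd3 was higher (0.22 ± 0.06), and Tspo and the bile acid enzyme gene Hsd3b7 (-0.74 ± 0.2) lower, 17 of 20 not passing (3 higher and 2 lower adjusted over the list alone). Without wild-type LPS replicate 1 the count of 1935 called genes became 4005; it became 1088, 858 and 958 without wild-type LPS replicates 2, 3 and 4, and 1273 and 1035 without knockout LPS replicates 2 and 3. A fit of these 8 libraries alone called 438 genes.

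**Figure D3:**
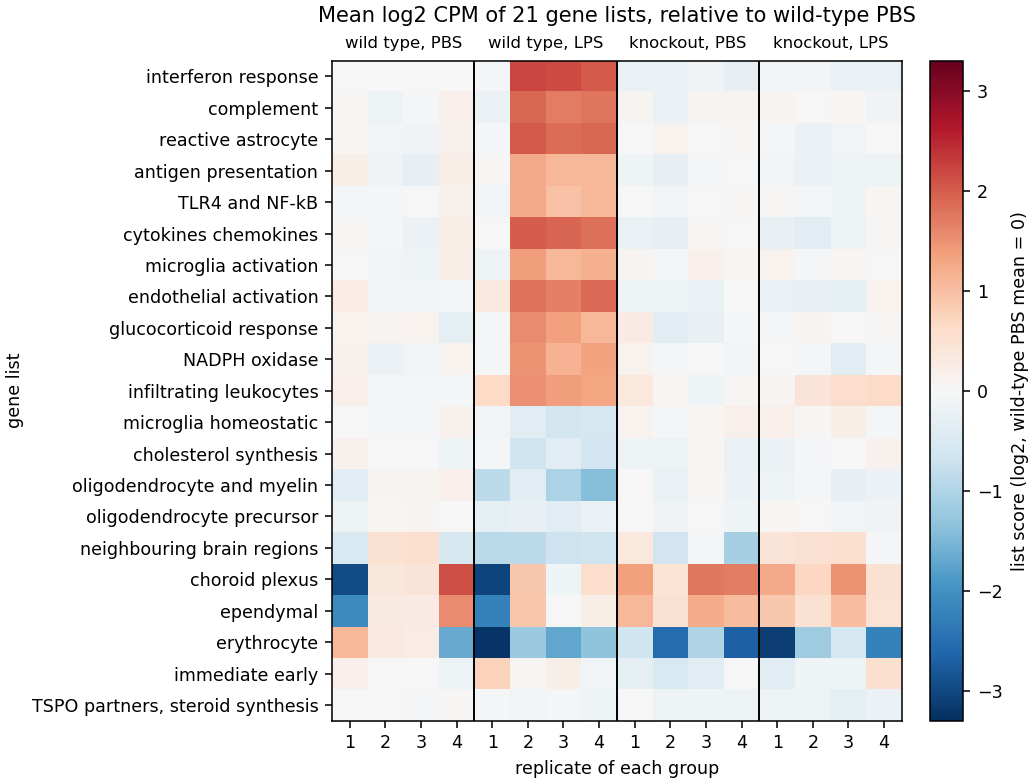
Mean log2 CPM of 21 gene lists in each library, set to 0 at the wild-type PBS mean; columns are replicates 1 to 4 of each group and colours run from low (blue) to high (red). The interferon list was at 2.03 to 2.2 in wild-type LPS replicates 2, 3 and 4 and at most 0.02 in the PBS libraries, while choroid plexus and ependymal lists were low in wild-type PBS replicate 1 (-2.94 and -2.11) and wild-type LPS replicate 1 (-3.05 and -2.24).

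The interaction tests whether the response to LPS differs between the genotypes. It called 187 genes, 90 with a higher and 97 with a lower response in the knockout (smallest adjusted p = 0.0349). In the 10 genes with the smallest p, all 4 wild-type LPS libraries lay on the same side of the 4 wild-type PBS libraries. Sccpdh, a lipid droplet protein gene, fell in wild type from 63.8 ± 3.14 to 43.1 ± 3.24 CPM and stood at 56.8 ± 2.49 and 58.1 ± 1.75 CPM in the knockout (mean ± SD, n = 4; interaction 0.6 ± 0.08, SE). Echdc1, which clears a toxic metabolite of fatty acid synthesis (0.52 ± 0.08), Wls, which escorts Wnt proteins to the surface (0.91 ± 0.14), and the homeobox gene Nkx2-9 (3.06 ± 0.48) also fell in wild type and had a higher response in the knockout. So did the serine protease gene Tmprss5 (2.42 ± 0.38), Smyd1 (2.27 ± 0.38) and the kinase activator gene Mob3b (1.28 ± 0.22). Mamstr, a cofactor of the transcription factor MEF2 (-1.2 ± 0.2), Sbsn, a secreted epithelial protein gene (-0.88 ± 0.15), and Slc25a28, the mitochondrial iron carrier mitoferrin-2 (-0.65 ± 0.11), rose in wild type and had a lower response in the knockout. Lcn2 (-11.26 ± 5.3, adjusted p = 0.234), Cfb (-5.58 ± 1.34, adjusted p = 0.0535), Icam1 (-2.72 ± 0.71, adjusted p = 0.0637) and Tspo (-2.76 ± 0.94, adjusted p = 0.117) did not pass. Without wild-type LPS replicate 1 Tspo passed (-3.06, adjusted p = 0.0291). Without the library labelled knockout PBS replicate 1 its interaction was -1.28 (adjusted p = 0.353). Of 37 interferon-stimulated genes 9 had a lower response in the knockout and 0 a higher one (30 lower adjusted over the list alone; adjusted p = 0.505 with an estimated correlation). Of 20 oligodendrocyte genes 2 had a higher one (13 adjusted over the list alone; adjusted p = 0.505 with an estimated correlation). Of 26 marker genes of neighbouring brain regions 2 had a higher one too (7 adjusted over the list alone; median 0.69; adjusted p = 0.505 with an estimated correlation). Leaving out any library except wild-type PBS replicate 1 moved the count of 187 beyond 1.5 times. It was 0, 0 and 947 without wild-type PBS replicates 2, 3 and 4, and 2655, 43, 0 and 1 without wild-type LPS replicates 1 to 4. It was 3, 0, 0 and 1 without the libraries labelled knockout PBS replicates 1 to 4, and 0, 0, 1 and 0 without knockout LPS replicates 1 to 4. With edgeR, 3520 genes had an unadjusted p below 0.05, and DESeq2 called 1300 and limma-voom with sample weights 4029. The count fell to 63 with RLE size factors, 39 without a filter on low counts, 42 with a stricter filter and 40 with sex as a covariate. With 1 surrogate variable it was 0, so that none of the 10 genes named here passed.

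Under PBS, the comparison asks what the knockout changes without a challenge, and 6 genes passed, 841 having an unadjusted p below 0.05. Snx29, an endosomal sorting protein gene on chromosome 16, was lower at 3.79 ± 0.962 against 10.4 ± 0.503 CPM (mean ± SD, n = 4; log2 fold change -1.45 ± 0.16, SE; adjusted p = 0.0039). Higher were the pseudogenes Tmem181c-ps (1.59 ± 0.2) and Tmem181b-ps (0.99 ± 0.13) of a membrane protein gene, the dynein light chain gene Dynlt1b (0.88 ± 0.12), all on chromosome 17, and the olfactory receptor gene Olfr648 on chromosome 7 (0.97 ± 0.15). The predicted gene Gm20075, outside the naming rule and named after its values were seen, held at most 0.348 CPM in wild-type PBS and 19.9, 0.91, 20.9 and 36.3 CPM in the 4 libraries labelled knockout PBS. Of the 31-base words of Gm20075, 90.4% also occur in Btf3l4, of those of Tmem181c-ps 77.8% occur in Tmem181b-ps, and of those of Dynlt1b 82.7% occur in Dynlt1c, so that the separate levels of these copies are uncertain. Olfr648 shares 3.5% of its words with Tmem181b-ps, so its level may not be independent of that copy. The library labelled knockout PBS replicate 1 lay among the other libraries labelled knockout in Snx29 and Tmem181b-ps, with Snx29 at 3.73 CPM and Tmem181b-ps at 118 CPM. Wild-type LPS replicate 1 held Tmem181b-ps at 113 CPM and Olfr648 at 27.9 CPM, levels of the knockout libraries. Leaving out wild-type PBS replicate 1, 2 or 3 reduced the 6 genes to 3, 1 and 1, and DESeq2 called 19.

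**Figure D4:**
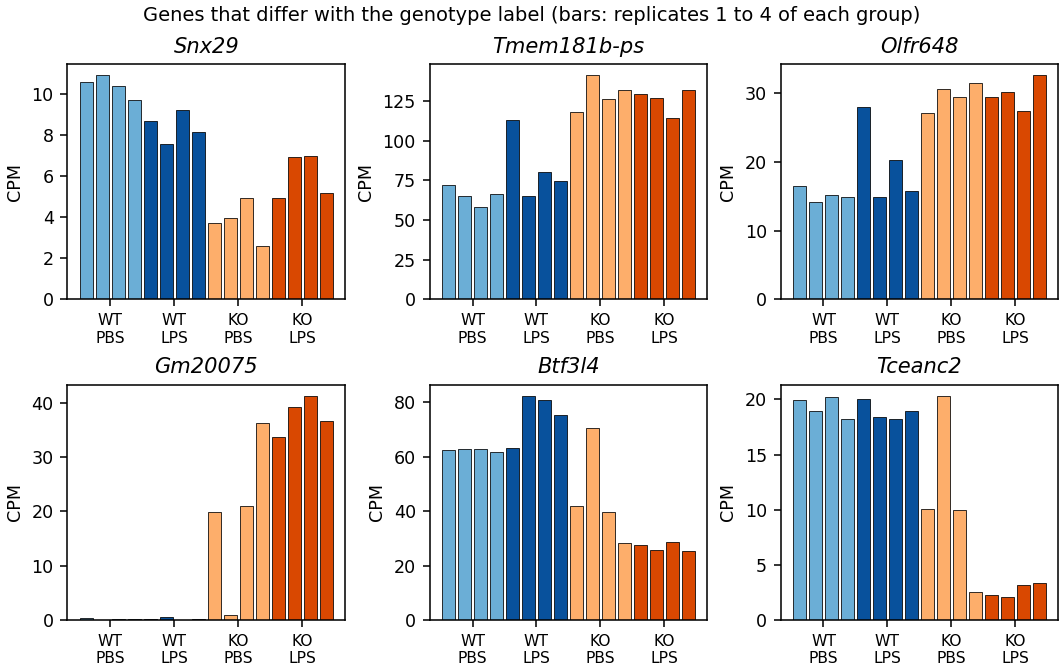
CPM of 6 genes in each library, with replicates 1 to 4 of each group as bars. Snx29 separated the genotype labels in all 16 libraries, Tmem181b-ps and Olfr648 were at the knockout level in wild-type LPS replicate 1 as well. Gm20075, Btf3l4 and Tceanc2 took intermediate levels in the libraries labelled knockout PBS replicates 1 and 3; in replicate 2 Btf3l4 and Tceanc2 were at the wild-type level and Gm20075 at 0.91 CPM, against at most 0.56 CPM in wild type.

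No list had a member that passed under PBS, and the preset correlation called 14 of 43 lists (0 with an estimated correlation), 5 as higher and 9 as lower. Without wild-type PBS replicate 1, whose choroid plexus and ependymal scores were -2.94 and -2.11, it called 1 list as higher and 8 as lower. Choroid plexus genes were higher in the libraries labelled knockout (median log2 fold change 0.48), and so were ependymal genes (0.44), both with an adjusted p of 0.645 with an estimated correlation. Red blood cell genes (-2.06, adjusted p = 0.642 with an estimated correlation), endothelial genes (-0.21, adjusted p = 0.532 with an estimated correlation) and pericyte and smooth muscle genes (-0.24, adjusted p = 0.642 with an estimated correlation) were lower. For the TSPO-binding and neurosteroid genes the list test gave an adjusted p of 0.243, with 0 of 20 members passing, also adjusted over the list alone.

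The genotype effects under PBS and under LPS, which share no libraries, correlated across the 16269 genes at r = 0.043 (jackknife SE 0.093; permutation p = 0.644 from 100 draws of genotype labels within treatments). The LPS responses of wild type and knockout correlated at r = -0.056 (jackknife SE 0.104; permutation p = 0.545 from 100 draws of treatment labels within genotypes). Genes are not independent replicates, and each r lay closer to 0 than its SE.

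Marker genes of neighbouring tissue varied between libraries of the same group; the genes in the next sentences were named after their values were seen. Ttr, the choroid plexus transport protein gene, held 1.42 CPM in wild-type PBS replicate 1 and 1.5 CPM in wild-type LPS replicate 1, against 518 to 3120 CPM in the other 14 libraries. Cbln3 and Pcp2, genes of cerebellar neurons, held 302 and 65.3 CPM in the library labelled knockout PBS replicate 2 and at most 1.36 and 0.348 CPM elsewhere. Prkcd, abundant in thalamus, held 294 and 299 CPM in wild-type PBS replicates 2 and 3 and 188 CPM in knockout LPS replicate 2, against 10.2 to 44.3 CPM in wild-type LPS. Tnnt1, Synpo2 and Plekhg1, named above as higher in the knockout under LPS or as falling in wild type, were likewise highest in wild-type PBS replicates 2 and 3, with Synpo2 at 80.4 and 81.1 CPM there and 6.35 to 15.1 CPM in wild-type LPS. The beta-globin gene Hbb-bs ranged from 4.48 to 279 CPM.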

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

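All explanation tests in this part were chosen only after the result was seen, except the counts of other splits of the libraries, which were planned.

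An interferon response to LPS was missing in the libraries labelled knockout LPS and wild-type LPS replicate 1. That replicate lay apart from the rest of its group in 58 named genes and in the list scores of interferon-stimulated genes (-0.04), cytokines and chemokines (-0.02), complement (-0.19), antigen presentation (0.04). The same held for reactive astrocytes (-0.04), activated endothelium (0.31), fatty acid oxidation (-0.17) and antioxidant genes (-0.16). By Y-linked genes, wild-type LPS replicate 1 was also the only male library of its group. Knockout LPS replicates 1 and 2 lacked the interferon response too and were female. A swap of libraries between PBS and LPS groups is argued against, since the highest interferon score among the 8 PBS libraries was 0.02. A missing or differently timed exposure may explain the pattern and stays open. The leukocyte score of knockout LPS against knockout PBS gave an exact permutation p of 0.0571. It was 0.08, 0.42, 0.59 and 0.64 in knockout LPS replicates 1 to 4. In wild-type LPS replicate 1 it was 0.67, and in the PBS libraries at most 0.35. This score bears only on a missing exposure, since a different time need not prevent a rise. The title codes do not settle the exposure. The library labelled knockout PBS replicate 4 shares that of wild-type LPS replicates 2, 3 and 4 with an interferon score of -0.28. Loss of Tspo also stays open, but cannot be told apart from a missing or differently timed exposure, because wild-type LPS replicate 1 had an interferon score of -0.04 with Tspo at the wild-type level.

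The library labelled knockout PBS replicate 1 held Tspo at 2.33 CPM, far from the rest of its group. A swap with a wild-type library is argued against, since the lowest Tspo among the 8 wild-type libraries was 2.06 CPM and no wild-type library held a knockout level. Its Lcn2 level of 0.0237 CPM argues against carry-over from a wild-type LPS library. An animal of the wild-type line under a knockout label is argued against by all 3 genes in which the median of the other 7 knockout-labelled libraries lay beyond the wild-type range by more than that range, since this library did so too, with Snx29 at 3.73 CPM (wild type 7.54 to 10.9), Gm20075 at 19.9 CPM (at most 0.56) and Cmss1 at 1.76 CPM (5.55 to 6.98). A measure tried earlier, its median position between wild type (0) and knockout (1), was 0.83 and decided nothing, as wild-type PBS replicate 4 lay at 1.07 by it. No biological explanation was tested.

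Genes that differed between knockout and wild type under PBS were weighed for families of similar sequence. No explanation was tested for Snx29. For Olfr648 the words shared with Tmem181b-ps were counted, but whether shared reads account for its rise was not tested. For Gm20075, reads divided between it and Btf3l4 may be the source, since their summed CPM differed by only 0.05 on the log2 scale. For the Tmem181 copies a division of reads is argued against, as their sum rose by 0.74. The family sum of Dynlt1b (0.88) rose by 0.34 ± 0.14 (SE). By the limit applied to the other sums, a division as the only source is argued against too. Its groups overlapped, with 24.1 CPM in the library labelled knockout PBS replicate 4 and 25.8 CPM in wild-type PBS replicate 1, so a partial division stays open. A background variant not tied to the Tspo deletion is a candidate explanation for the Tmem181 copies, since wild-type LPS replicate 1 held a sum of 306 CPM, in the knockout range. Loss of Tspo stays undecided for Gm20075, whose lowest level among the 7 knockout-labelled libraries with low Tspo was 0.91 CPM. That was in the library labelled knockout PBS replicate 2, with Tspo at 0.152 CPM. The library labelled knockout PBS replicate 1, with Tspo at 2.33 CPM, held far more Gm20075. Both go against a loss of Tspo as the source, but each is 1 library.

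Chance flags about 1 in 20 groups; here 20 of 172 group tests of list scores and 101 of 720 of named genes lay apart. Besides those above, the lists were complement in the library labelled knockout PBS replicate 2 (-0.22), TSPO-binding and neurosteroid genes in knockout LPS replicate 3 (-0.29), and pericyte and smooth muscle genes in the same library (-0.5). In wild-type PBS replicate 4 they were astrocyte markers (-0.16), interneurons (-0.14) and glucocorticoid-responsive genes (-0.31), and in wild-type PBS replicate 1 oligodendrocyte genes (-0.36), activated endothelium (0.24) and leukocyte genes (0.18). The others were neurogenesis genes in the library labelled knockout PBS replicate 2 (0.45), the citric acid cycle in the library labelled knockout PBS replicate 3 (0.02) and synaptic genes in the library labelled knockout PBS replicate 4 (0.13). Scores were tested after rounding, and the citric acid cycle score was 0.03 in the rest of that group. That flag, 1 of the 20, thus reflects a rounding step and not a library that lay apart. Named genes lay apart in wild-type PBS replicates 1 and 4 (10 and 9 genes), wild-type LPS replicates 2, 3 and 4 (2, 1 and 2). They did so too in the libraries labelled knockout PBS replicates 1 to 4 (7, 4, 2 and 1) and knockout LPS replicates 1, 3 and 4 (2, 1 and 2).

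The response to LPS differed between the genotypes in 187 genes and 20 lists, by the interaction test with a preset correlation for the lists; 0 lists were called with an estimated correlation and 0 with fry. The 10 genes named for it had interaction log2 fold changes of 0.6 (Sccpdh), 0.52 (Echdc1), 0.91 (Wls), 3.06 (Nkx2-9), 2.42 (Tmprss5), 2.27 (Smyd1), 1.28 (Mob3b), -1.2 (Mamstr), -0.88 (Sbsn) and -0.65 (Slc25a28). Among 100 draws of genotype labels within treatments only the real one called as many as 187, and the highest other, with the genotypes exchanged under 1 treatment, called 149. The real labels were 1 of the 100, so the draws can give no share below 1 in 100. Most draws divided wild-type LPS replicates 2, 3 and 4 between the genotypes, whereas the real labels and the draw with 149 genes kept them together. The genotypes also share no title code within a treatment, so the libraries need not be exchangeable. The draws therefore cannot say whether the interaction count is chance. The count was 0 with a surrogate variable and with the summed libraries. By splits of the libraries, chance cannot be excluded for the counts under PBS, under LPS and in wild type. Under PBS, 2 of 35 splits called at least the real 6 genes, with 13 as the highest other. Under LPS, 2 of 35 called at least 1935, with 1962 as the highest other, for wild-type LPS replicate 1 grouped with knockout LPS replicates 2, 3 and 4. In wild type, 2 of 35 called at least 1394, with 2952 as the highest other. It grouped wild-type LPS replicate 1 with wild-type PBS replicates 1, 2 and 3 and points to a structure of these libraries other than their labels. The highest other splits under LPS and in wild type both kept wild-type LPS replicates 2, 3 and 4 together. They therefore hold the inflammatory rise of those libraries and cannot say whether that rise is chance. In the knockout, where 0 genes were called by edgeR (1120 at an unadjusted p below 0.05; 3 by DESeq2), all 35 splits necessarily gave at least as many, with 7 as the highest other, so that they say nothing about chance.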

How the results depend on the processing

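Summing wild-type PBS replicates 2 and 3 and setting aside 3 libraries of different tissue composition were chosen only after the result was seen. Of the 280 named gene results, 0 reversed under any alternative; 1 lost its call with DESeq2, 5 with voom weights, 180 of 245 in the 8 libraries compared, and 4 to 104 when a library was left out. The cause was not tested for any change below.

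Genes called under PBS (6) became 19 with DESeq2, 308 with voom weights, 3 with the replicate block, 1 with the summed libraries, and 1 to 9 leaving out a library. Under LPS (1935) they became 4073 with voom weights, 438 in the 8 libraries, 4205 without the 3 libraries, and 858 to 4005 leaving out a library. In wild type (1394) they became 2150 with DESeq2, 4684 with voom weights, 0 by edgeR in the 8 libraries (3012 at an unadjusted p below 0.05), 670 with the summed libraries, 3215 without the 3 libraries, and 538 to 3380 leaving out a library. In the knockout (0 by edgeR; 1120 at an unadjusted p below 0.05; 0 with voom weights) DESeq2 called 3, and leaving out a library gave 0 to 1. Interaction genes (187) became 63 with RLE, 1300 with DESeq2, 4029 with voom weights, 39 without a filter and 42 with CPM of at least 1 in 4 libraries. They became 0 with the replicate block, 40 with sex, 0 with a surrogate variable, 0 with the summed libraries, 2201 without the 3 libraries, and 0 to 2655 leaving out a library.

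Tspo in wild type (1.46) passed with voom weights (1.91) and without the 3 libraries (1.68), ranging from 1.25 to 1.83 leaving out a library. Its interaction (-2.76) passed with DESeq2 (-2.74), voom weights (-2.45), without the 3 libraries (-3.31) and without wild-type LPS replicate 1 (-3.06), ranging from -3.12 to -1.28 leaving out a library. Tspo in the knockout (-1.29) reversed to 0.18 without the library labelled knockout PBS replicate 1, ranging from -1.62 to 0.18. The correlation of LPS responses (-0.056) ranged from -0.089 to 0.022 leaving out a library. The difference under PBS ranged from -3.37 to -1.52 and that under LPS from -4.94 to -4.44 leaving out a library, with the same calls. Lists called with an estimated correlation were 0 under PBS (of 14), 0 under LPS (of 23), 1 in wild type (of 23), 0 in the knockout (of 7) and 0 for the interaction (of 20). With fry they were 0 under PBS, in the knockout and for the interaction, 21 under LPS and 16 in wild type. Leaving out a library gave 9 to 17 lists under PBS and 5 to 11 in the knockout, and 13 without the 3 libraries. The correlation of genotype effects (0.043) was 0.146 with a surrogate variable and -0.002 to 0.112 leaving out a library. The numbers do not pair the samples: 2 of 24 same-number pairs correlated above 0.1, with a median of 0.006 against -0.002 for other pairs. Of 67 simulated changes of 1.5-fold, 38.8% were recovered in the interaction and 59.7% in the knockout. Small changes were thus missed even in simulated data, which held no tissue differences between libraries.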

Other observations

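The values in this part were picked only after the result was seen. Counts of wild-type PBS replicates 2 and 3 lay closer together than those of any other pair within a group, with a mean chi-square of 4.02 per gene against at least 13.2 for the other pairs. The labels do not say whether they come from separate animals; if not, wild-type PBS holds 3 independent samples rather than 4. Entered as 1 library, they took the count of called genes from 1394 to 670 in wild type and from 187 to 0 for the interaction (edgeR).

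Tceanc2 held 10.1, 20.3, 9.99 and 2.55 CPM in the libraries labelled knockout PBS replicates 1 to 4, against 18.2 to 20.2 CPM in wild type and 2.1 to 3.34 CPM in knockout LPS. Across the libraries labelled knockout PBS, its order was the reverse of that of Gm20075.

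By their Y-linked genes, wild-type PBS replicate 4, wild-type LPS replicate 1, the libraries labelled knockout PBS replicates 2 and 3, and knockout LPS replicates 3 and 4 were male, and the other 10 libraries female.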
